A study of Mus musculus with 6 samples.

How the data were processed

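RNA sequencing counts from 6 libraries of MMTV-PyMT mouse mammary tumour cells were analysed, 3 from cells labelled quiescent cancer stem cells (CSCs) and 3 from cells labelled activated CSCs. MMTV-PyMT mice carry the polyoma virus middle T antigen under a mammary promoter and develop mammary tumours. Total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say how the cells were sorted or activated. They also do not say whether the libraries of a state came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

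The deposited values were raw counts per gene for 41795 features, per the file headers and the values, which were whole numbers with different totals in each library. HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 are named in the submitters' processing notes, without roles. The genome coordinates in the file use the accessions of GRCm38, and the counting strand is not given in the sources used here. Of the feature identifiers, 96.4% were found in a RefSeq gene table of GRCm38. Another 187 features were unannotated loci without a gene name, with 0.144 to 0.239% of the counts of a library, and were kept. Gene copies that are nearly identical, overlapping genes and antisense genes may share reads in such counts. Totals ran from 17785331 to 20510377 counts per library, and levels are given as CPM, the counts scaled to a common library total. At the lowest named levels a value rests on few counts. Intervals of count ratios cover counting error only. The Setd4 interval comes from the spread between libraries, and intervals of list medians are bootstraps over genes.

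The test, the samples, the gene lists and the rule for named genes were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test with robust estimation, TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Adjusted p for genes come from this test on all 6 libraries unless another setting is named beside them. Levels are printed as mean ± SD over 3 libraries, and log2 fold changes are activated over quiescent with their standard error (SE). In total 38 gene lists were fixed, and 34 of them had at least 5 tested genes. These were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, fry was run beside it, and each list's median was set against 10000 random lists of equal size matched on expression.

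Named genes were Setd4, a set of preset focus genes, up to 2 members of each list with the smallest adjusted p, and the 8 protein-coding genes with the largest change in each direction. The last group needed an adjusted p under the threshold, a mean of at least 5 CPM and every library of a state above every library of the other. Other genes named below were chosen after their values were seen. Libraries were compared by a chi-square test of their counts. All pairs within a state differed by more than sampling noise, and all 6 libraries were used. Ratios of chi-square to degrees of freedom were 5.53 and 6.03 for the pairs with activated replicate 1. They were 1.98 to 3.33 for the other pairs within a state. This test left out genes with a mean under 20 counts and the genes with unstable counts defined below.

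The fit was tested on simulated data with the means and library sizes of 15223 genes, of which 200 were changed. In this simulation 32% of genes changed 1.25-fold were recovered and 62% of those changed 1.5-fold. The share was 84% at 2-fold and 94% at 4-fold. Of 151 simulated calls, 15 (9.93%) were genes that had not been changed, above the nominal 5%. The data gave 7236 calls, far more than the 200 genes changed here, so the adjusted threshold falls at another p. The shares recovered and falsely called may therefore differ in the data. Of 30 simulated lists 3 were moved, and each of these was recovered, with 0 false calls among the rest. The simulated genes were drawn independently, so this does not test the set calls for lists with correlated genes. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters and thresholds, protein-coding genes alone, no mitochondrially encoded genes, the replicate number as a block and leaving out each library. Leaving out 184 genes with unstable counts, defined as a highest CPM within a state over 3 times the lowest with a floor of 1 CPM, was added after seeing the data. Shared sequence was measured as 31-base words of the longest GENCODE M21 transcript of a gene that were also found in another gene.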

Results

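RNA was sequenced from mouse mammary tumour cells in 2 states, quiescent and activated CSCs, with 3 libraries each. CSCs are tumour cells that can renew themselves and regrow a tumour, and quiescent CSCs are those resting outside the cell cycle. Quiescent libraries held 17785331, 18479886 and 19145576 counts, and activated libraries held 17842568, 18286626 and 20510377. The 20 most abundant genes took 8.24 to 8.39% of the counts in quiescent and 9.36 to 9.49% in activated libraries. Mitochondrially encoded genes took 2.12 to 2.29% over all 6. The first principal component of the 500 most variable genes held 69.6% of the variance and separated the states, and the second held 8.73%.

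The comparison asked how the transcriptome of activated CSCs differed from that of quiescent CSCs. Genes of mitosis and DNA replication were higher in activated CSCs, with Mki67, a marker of cycling cells, rising from 49.8 ± 1.37 CPM to 239 ± 19.4 CPM (SD, n = 3), 4.8-fold. Both lists had an adjusted p = 0.059 with an estimated correlation, short of the threshold. Mki67 had 876, 949 and 928 counts in the quiescent libraries, so it was expressed there too. The share of cycling cells was not measured. Targets of the tumour suppressor p53 and detoxification genes were lower, with Gdf15, a stress-induced cytokine, falling from 107 ± 6.72 to 8.99 ± 0.757 CPM and Slc7a11, the cystine transporter, from 627 ± 29 to 66.8 ± 2.13 CPM. These lists also had an adjusted p = 0.059 with an estimated correlation. Milk and alveolar genes were higher and inflammatory cytokine genes lower, with an adjusted p = 0.11 and an adjusted p = 0.15 with an estimated correlation. Setd4, the methyltransferase gene named in the study's title, did not pass the threshold.

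Of 15223 genes tested, 7236 changed, 3668 of them higher and 3568 lower in activated CSCs. Higher and lower are relative to the other genes of a library after scaling, and RNA per cell was not measured. At a log2 fold change of at least 1 in either direction, 1420 genes remained, 904 higher and 516 lower. Counts varied little within a state, with a common biological coefficient of variation of 9.23%. In 55.9% of genes the states did not overlap, against 10% by chance.

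Setd4 (NCBI gene 224440, GRCm38 chromosome 16, 93583457 to 93604770, minus strand) was at 9.54 ± 0.644 CPM in quiescent and 9.71 ± 0.371 CPM in activated CSCs. Its log2 fold change was 0.03 (SE 0.11, adjusted p = 0.87), with a 95% interval from -0.2 to 0.25. That interval covers folds from 0.871 to 1.19, on 158 to 193 counts per library.

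**Figure D1:**
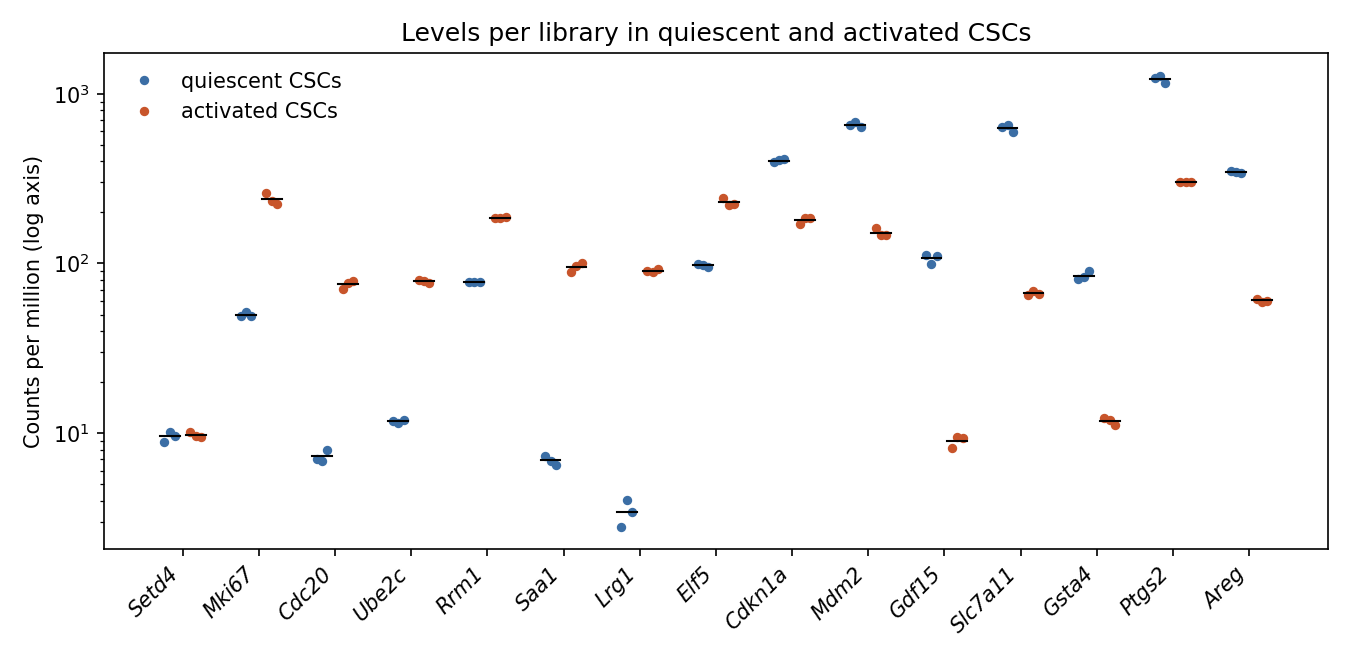
CPM of 15 genes in each library, on a log axis, with points for the 3 libraries of a state and a black line at their mean. Setd4 lies near 9.54 CPM in quiescent and 9.71 CPM in activated CSCs, while the 3 libraries of each state are apart from those of the other for the other genes shown.

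Genes that act in mitosis moved together. Of 38 tested members of the mitosis and G2/M list 37 rose and 1 did not pass, with a median log2 fold change of 2.21. Cdc20, an activator of the anaphase-promoting complex, rose from 7.3 ± 0.603 to 75.5 ± 4.31 CPM (log2 3.37, SE 0.07, adjusted p = 1.2e-15), and Ube2c, its partner ubiquitin-conjugating enzyme, rose 6.69-fold. Of 40 DNA replication and G1/S genes 37 rose and 3 did not pass, with a median of 0.58. Among these Rrm1, a subunit of ribonucleotide reductase, rose 2.39-fold and Tk1, thymidine kinase, 2.49-fold. Of 38 DNA repair and damage checkpoint genes 28 rose and 1 fell (median 0.38), including Fancd2 at 3.22-fold and Brca1 at 2.1-fold. The counts that rose were 37, 37 and 29 when adjusted over the list alone. Camera called the lists at adjusted p = 7.5e-25, 2.3e-12 and 1.8e-07. None was called with an estimated correlation, where the adjusted p = 0.059, 0.059 and 0.098 with an estimated correlation.

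Cell cycle inhibitors did not move in a single direction. Of 28 tested members of the inhibitor and quiescence-associated list 16 rose, 6 fell and 6 did not pass, with a median of 0.33. Cdkn1a, which encodes the inhibitor p21, fell from 404 ± 9.08 to 181 ± 8.32 CPM (log2 -1.16, SE 0.04, adjusted p = 4.5e-13). Cdkn1b, which encodes p27, rose from 51.6 ± 1.29 to 74.4 ± 1.34 CPM, and Rb1, the retinoblastoma gene, rose 2.72-fold. Adjusted over the list alone, 18 rose and 6 fell. The list was called higher (camera adjusted p = 0.013), with an adjusted p = 0.17 with an estimated correlation.

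The p53 target list was lower in activated CSCs, with 22 of 26 members falling, 1 rising and 3 not passing (median log2 -0.73). Mdm2, the ubiquitin ligase that restrains p53, fell from 658 ± 22.1 to 152 ± 8.28 CPM (log2 -2.12, SE 0.05, adjusted p = 9.4e-16). Of 33 drug efflux and detoxification genes 20 fell, 3 rose and 10 did not pass (median -0.65), with Gsta4, a glutathione transferase, falling from 84.9 ± 5.27 to 11.8 ± 0.538 CPM. Aldh3a1, an aldehyde dehydrogenase, fell from 64 ± 5.45 to 8.09 ± 0.379 CPM, and Akr1c18, an aldo-keto reductase, from 36 ± 1.51 to 5.59 ± 0.878 CPM. When adjusted over the list alone, 23 p53 targets and 21 detoxification genes fell. Camera gave adjusted p = 3.2e-10 and 5.4e-07, and both lists had an adjusted p = 0.059 with an estimated correlation.

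Inflammatory and lysosomal genes were lower. Of 25 NF-kB and inflammatory cytokine genes 16 fell and 2 rose (median -0.41), with Ptgs2, the inducible prostaglandin synthase, falling from 1230 ± 59.6 to 301 ± 1.37 CPM and Csf3 from 254 ± 10.9 to 83.3 ± 1.83 CPM. Of 34 autophagy and lysosome genes 20 fell and 4 rose (median -0.18), with Sqstm1, an autophagy receptor, at 1220 ± 31.2 and 620 ± 12.1 CPM and Ctsl, a lysosomal protease, at 1410 ± 46.1 and 695 ± 21 CPM. The counts that fell were also 16 and 20 when adjusted over the list alone. Camera gave adjusted p = 4.6e-05 and 0.0034, against adjusted p = 0.15 and adjusted p = 0.29 with an estimated correlation. Slpi, a secreted protease inhibitor, fell from 1170 ± 47.8 to 204 ± 26.8 CPM, and Klk7, a secreted protease, from 96.8 ± 2.8 to 16.3 ± 1.02 CPM.

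Acute phase and other secreted genes were among the named genes with the largest increases. Saa2 rose from 1.72 ± 0.133 to 58.4 ± 5.09 CPM (log2 5.08, SE 0.1, adjusted p = 5.3e-16) and Saa1 from 6.92 ± 0.428 to 95.2 ± 5.37 CPM, both serum amyloid A genes on chromosome 7 whose similar sequences may share reads. Lrg1, a secreted glycoprotein, rose from 3.43 ± 0.623 to 90.4 ± 1.64 CPM, and Fcgbp, a mucin-like protein, from 1.75 ± 0.403 to 60.5 ± 2.17 CPM. Wisp2 rose 13-fold and Prtn3 10.4-fold, and Pif1, a DNA helicase, rose 20-fold from 0.504 ± 0.157 CPM. Of 16 alveolar and milk genes 14 rose and 0 fell (median 1.17), with Elf5, a transcription factor of alveolar cells, at 97.4 ± 2.02 and 230 ± 10.6 CPM and the receptor gene Kit at 71.7 ± 2.71 and 173 ± 1.13 CPM. Csn1s2a, a casein gene of this list, had 1 count over the quiescent and 51 over the activated libraries, a ratio of 49.9 in CPM with a 95% counting interval from 8.56 to 2010 (exact Clopper-Pearson). Adjusted over the list alone, 14 rose, and camera gave an adjusted p = 3.2e-07 against an adjusted p = 0.11 with an estimated correlation.

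Markers of fibroblasts and of myeloid cells were higher in the same libraries as these groups. Of 16 fibroblast markers 13 rose and 0 fell (median 0.62), with Col3a1 at 111 ± 1.3 and 306 ± 9.39 CPM and Col1a2 at 237 ± 7.76 and 366 ± 13.8 CPM, while Pdgfra was at 39 ± 1.89 and 40.1 ± 3.19 CPM. Of 18 macrophage and myeloid markers 10 rose and 1 fell (median 0.38), with Cd14 at 441 ± 8.79 and 702 ± 9.31 CPM and Cd163 at 10.7 ± 0.456 and 29.3 ± 1.53 CPM. Ptprc, the pan-leukocyte gene, was at 5.73 ± 0.503 and 7.13 ± 0.719 CPM (adjusted p = 0.065, and 0.026 without activated replicate 1). Which cells the myeloid marker counts came from was not tested. Adjusted over the list alone, 14 fibroblast and 11 myeloid markers rose. Camera gave adjusted p = 1.9e-06 and 0.0042, against adjusted p = 0.059 and adjusted p = 0.29 with an estimated correlation.

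Beside these markers, genes of the matrix and of the mesenchymal state were higher. Of 26 mesenchymal genes 15 rose and 1 fell (median 0.28), with Mmp9, a matrix protease, rising 4.29-fold, Tgfb3 2.37-fold and Vim, vimentin, from 251 ± 10 to 350 ± 9.59 CPM. Of 31 matrix genes 18 rose and 9 fell (median 0.22), with Fbln2 at 2.74-fold and Col6a3 at 2.5-fold. Of 21 Notch pathway genes 9 rose and 4 fell (median 0.24), with the target Hey1 at 3.4-fold and the ligand Dll1 at 2.66-fold. As many members of each, 15, 18 and 9, rose when adjusted over the list alone. Camera gave adjusted p = 0.0064, 0.044 and 0.045, against adjusted p = 0.17, 0.18 and 0.18 with an estimated correlation. The matrix call ended with protein-coding genes alone (adjusted p = 0.053), without quiescent replicate 1 (0.079) and without activated replicate 2 (0.057). The Notch call ended with protein-coding genes alone (adjusted p = 0.055), without quiescent replicate 1 (0.053) and without activated replicate 3 (0.085).

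Metabolic and chaperone lists rose in part. Of 22 glycolysis genes 13 rose and 3 fell (median 0.32), with Aldoc at 5.36-fold and Aldoa at 1.97-fold. Gapdh, in the same list, had 75 to 98 counts in 4 libraries and 1052 and 2389 in the other 2, so its log2 of 3.71 (SE 1.32, adjusted p = 0.087) rests on unstable counts. Of 24 cholesterol synthesis genes 18 rose and 3 fell (median 0.32), with Cyp51 rising 1.49-fold and Dhcr7, of the last step, falling from 226 ± 9.04 to 123 ± 7.07 CPM. Of 26 unfolded protein response genes 17 rose and 7 fell (median 0.33). The chaperone genes Hsp90b1 and Hspa5 rose 2.01-fold and 1.71-fold, and Xbp1 2.02-fold. Among the members that fell were Asns (log2 -1.12), Chac1 (-1.52) and Trib3 (-0.82), which respond to amino acid shortage through the factor ATF4. Adjusted over the list alone, 13, 18 and 17 members of these lists rose. Camera gave adjusted p = 0.0027, 0.0022 and 0.023, against adjusted p = 0.42, 0.098 and 0.19 with an estimated correlation.

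Of 32 histone lysine methylation and heterochromatin genes 16 rose and 3 fell (median 0.15), and 17 rose adjusted over the list alone. Lmnb1, lamin B1, rose 1.86-fold and Dnmt1, the maintenance DNA methyltransferase, 1.53-fold. Suv420h2 (Kmt5c), which methylates histone H4, rose 1.46-fold, Cbx5, which encodes the heterochromatin protein HP1 alpha, 1.34-fold, and Suv420h1 (Kmt5b) 1.09-fold. The Suv420h1 call ended with DESeq2 (adjusted p = 0.057) and without quiescent replicate 1 (0.062), quiescent replicate 2 (0.058) or activated replicate 3 (0.057). The list was called higher (camera adjusted p = 0.01), with an adjusted p = 0.24 with an estimated correlation.

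Breast cancer stem cell markers went both ways. Of 21 tested members 10 rose, 8 fell and 3 did not pass (median -0.04), and 10 rose and 9 fell adjusted over the list alone. Tspan8 rose from 13.5 ± 1.02 to 57.7 ± 1.92 CPM and Itgb3 from 151 ± 2.62 to 332 ± 23.5 CPM. Prom1, which lies within 100 kb of a gene with unstable counts, rose 1.34-fold, and Cd24a rose from 488 ± 6.58 to 562 ± 35.7 CPM. Cd44 fell from 895 ± 20.9 to 649 ± 18.6 CPM and Epcam from 1600 ± 9.77 to 1170 ± 14.4 CPM, while Aldh1a1 was at 1.22 ± 0.569 and 0.604 ± 0.3 CPM (adjusted p = 0.062), and passed with no filter (0.023), without quiescent replicate 2 (0.033) and without activated replicate 3 (0.02). Lgr5 had 3 counts over the quiescent and 160 over the activated libraries, a ratio of 52.2 in CPM with a 95% counting interval from 17.5 to 256. The list as a set was not called (camera adjusted p = 0.7).

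Several other lists that were not called held members that moved in both directions. Among luminal hormone-responsive genes (6 higher, 2 lower of 14), Areg, an EGF receptor ligand, fell from 345 ± 5.79 to 60.5 ± 1.3 CPM. Among basal and myoepithelial genes (7 higher, 8 lower of 23), Krt17 fell from 486 ± 18.2 to 235 ± 6.07 CPM while Krt14 rose from 507 ± 16.8 to 626 ± 20.5 CPM. Among epithelial junction and keratin genes (7 higher, 13 lower of 30), Krt19 rose 2.7-fold, Cldn1 was at 461 ± 7.28 and 248 ± 4.32 CPM and Krt8 at 2430 ± 78.1 and 2320 ± 69.6 CPM (adjusted p = 0.18). Wnt genes (12 higher, 6 lower of 26) included Lgr6 at 3.58-fold and were called without quiescent replicate 2 (adjusted p = 0.047), and TGF-beta and BMP genes (11 higher, 10 lower of 28) included Ltbp2 at 3.36-fold. Immediate early and dissociation genes (13 higher, 8 lower of 28) included Fosb at 5.42-fold and Fos at 3.09-fold, and were called with no filter beyond 1 count (adjusted p = 0.047). Hypoxia genes (9 higher, 6 lower of 20) included Ndrg1 at 1.88-fold, and interferon genes split into 7 higher and 7 lower of 33.

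Oxidative phosphorylation genes mostly did not pass, with 2 higher, 8 lower and 33 not past of 43. Ribosome biogenesis genes split into 7 higher and 11 lower of 32, and mitochondrially encoded genes into 1 higher and 5 lower of 13, with ND5 at 2240 ± 101 and 1820 ± 88.6 CPM. Endothelial markers gave 1 higher and 2 lower of 10, pericyte markers 4 and 3 of 9, adipocyte markers 2 and 0 of 5 and skeletal muscle markers 1 and 1 of 6. Neutrophil, T and NK cell, B and plasma cell and erythroid lists had too few tested members for the set test. Among their members S100a8 was at 54.3 ± 1.84 and 65.6 ± 8.76 CPM and S100a9 at 1.74 ± 0.159 and 0.245 ± 0.0414 CPM, Trbc2 at 0.523 ± 0.0999 and 0.687 ± 0.0623 CPM, Cd22 at 1.75 ± 0.17 and 2.8 ± 0.589 CPM, Fcmr at 1.21 ± 0.229 and 0.505 ± 0.158 CPM and Klf1 at 0.455 ± 0.204 and 0.811 ± 0.186 CPM. Median and set test differed in sign for the stem cell markers (camera up), and fry was down for the luminal list, whose median was 0.14. In all, camera called 18 of 34 lists, 14 higher and 4 lower. With an estimated correlation it called 0, with 9 at an unadjusted p under 0.05, and fry called 28. The estimate was -0.02 for the p53 target and Notch lists and 0 for the cholesterol and matrix lists, below the preset value. For these lists the estimates argue against a higher correlation between genes as the reason the calls were lost. Their lost calls are thus no sign of correlated members. The other called lists had estimates from 0.01 to 0.32. No other reason for the lost calls was tested.

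**Figure D2:**
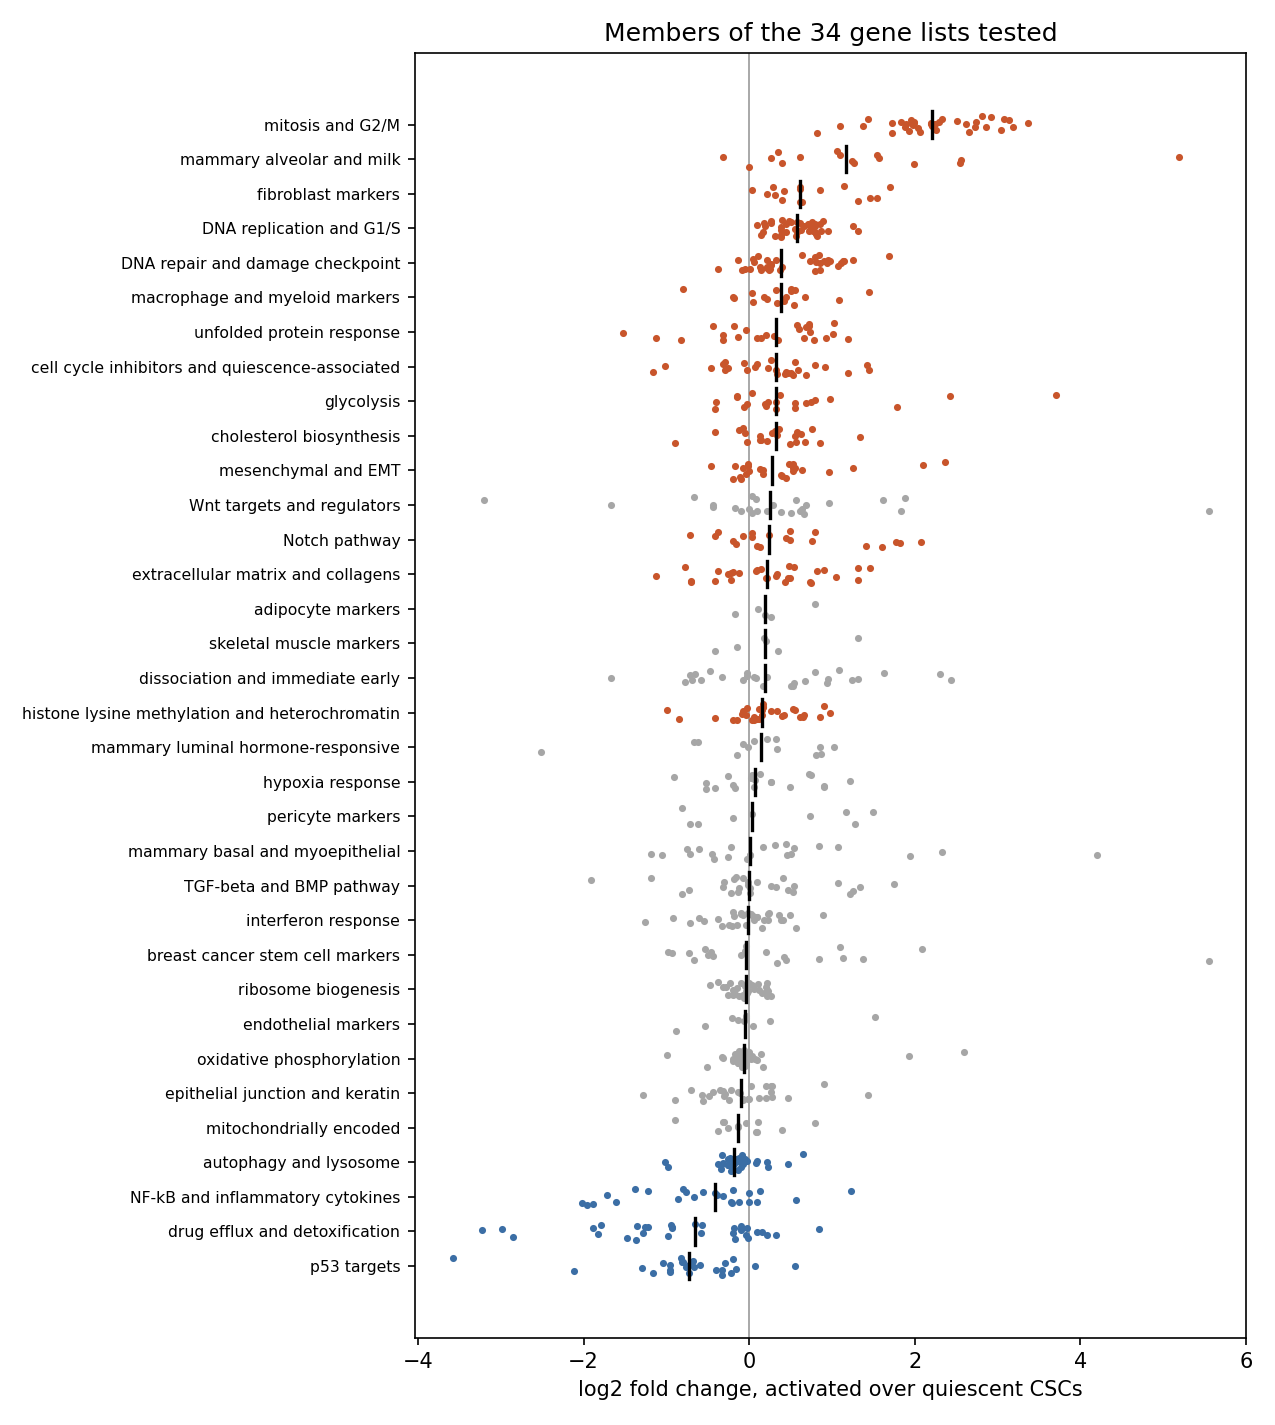
Log2 fold changes, activated over quiescent CSCs, of the tested members of 34 gene lists, with a point per gene and a black bar at the list median. Orange lists were called higher and blue lists lower by camera with a preset correlation, and grey lists were not called. The mitosis list has the highest median, 2.21, and the p53 target list the lowest, -0.73.

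Psmb6, a proteasome subunit gene (chromosome 11, 70525357 to 70527858), gave the lowest log2 fold change of the named genes, -5.74 (SE 0.17, adjusted p = 2.8e-08). It had 1160, 1197 and 1641 counts in the quiescent and 23, 28 and 25 in the activated libraries. Within 100 kb of it 4 genes had unstable counts, and their CPM swung between libraries of 1 state by 21.9-fold for Pld2, 4.18-fold for Mink1, 3.52-fold for Arrb2 and 3.1-fold for Cxcl16.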

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

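Leaving out the genes with unstable counts was chosen only after the result was seen, and the other settings were planned. The number of genes changed stayed between 5557 (adjusted p under 0.01) and 7700 (no filter beyond 1 count) wherever no fold threshold was set. DESeq2 called 6298, limma-voom 7058, and the fit without the unstable genes 7384. Leaving out each library gave 6387 to 7359 genes and 16 to 19 lists. None of the genes called in the planned fit changed sign in another setting. A log2 threshold of 1 left 1420 genes by construction. The number of lists called was 0 with an estimated correlation, 28 with fry in its directional form and 34 in its mixed form, and fry asks another question than camera. With random lists of matched expression 20 lists lay outside the central 95%. Setd4 stayed short of the threshold in every setting run, with log2 values from -0.02 to 0.07 when each library was left out.

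Deviations of same-numbered libraries had correlations of 0.01, -0.03 and 0.04, so no shared deviation was seen. Such values cannot tell whether the numbers pair the samples, which the labels do not say. With the replicate number as a block 7042 genes and 16 lists were called, and Setd4 had a log2 of 0.03. The Notch (adjusted p = 0.07) and matrix (0.074) lists lost their calls there. Of single genes the changes of S100a8, Cd22, Pparg, Acta1, Myh1 and Suv420h1 lost their calls in some settings, and the cause was not tested. For Setd4 the depth and spread left folds from 0.871 to 1.19 within its interval.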

Other observations

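The tests of the swinging counts, of the fibroblast markers and of NRF2 targets, and the count of other splits, were chosen only after the result was seen. So were the intervals in the test of GC content and length, whose bound of 0.2 was set before. The lists of ATF4 targets, of acute phase genes, of ionocyte genes and of the proteasome core were written before their members' values were seen.

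Of 22 ATF4 targets outside the fixed lists 16 fell, 0 rose and 6 did not pass, Slc7a5 (log2 0.09) and Shmt2 (0.08) among these. Their median log2 fold change was -0.49 (camera adjusted p = 3.7e-06, and adjusted p = 0.043 with an estimated correlation over the 5 added lists). Adjusted over all 39 lists, fixed and added, the adjusted p = 0.092 with an estimated correlation, and no list of the 39 was called. Phgdh, the first enzyme of serine synthesis, fell from 84 ± 5.82 to 32.1 ± 3.21 CPM and Slc3a2, the partner of Slc7a11, from 532 ± 6.21 to 280 ± 2.26 CPM. A candidate explanation for the lower Asns, Chac1 and Trib3 is lower ATF4 activity, a hypothesis that this list could have opposed and did not. Acute phase and STAT3 targets rose in 13 of 18 genes and fell in 0, with a median of 0.54 (adjusted p = 8.9e-05, and adjusted p = 0.043 with an estimated correlation over the added lists or 0.078 over all 39). Among them Lbp rose from 48.5 ± 2.4 to 145 ± 11.3 CPM and Hp from 7.3 ± 1.15 to 29 ± 1.58 CPM. The rise of Saa1, Saa2 and Lrg1 may thus be part of a broader acute phase response, as a hypothesis.

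Of 23 NRF2 targets outside the fixed lists 18 fell and 2 rose, with a median of -0.7 (adjusted p = 3.0e-07, and adjusted p = 0.043 with an estimated correlation over the added lists or 0.092 over all 39). The values of 3 members, Fth1, Slc48a1 and Esd, had been seen before the list was written. Without them 15 of 20 fell and the median was -0.58 (adjusted p = 1.1e-05, and adjusted p = 0.043 with an estimated correlation over the added lists or 0.088 over all 39). Lower NRF2 activity may underlie the lower detoxification genes, as a hypothesis. Foxi1 and Atp6v1b1 rose, but the other ionocyte and intercalated cell genes left a broader programme open. Only 11 of 22 were tested, 5 rose and 2 fell, and the median of 0.24 did not pass (adjusted p = 0.057).

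Unannotated loci whose description names a retroviral protein domain summed to 732 ± 35.1 CPM in quiescent and 441 ± 15.3 CPM in activated CSCs. Of 22 such loci 8 fell, 4 rose and 10 did not pass, with a median log2 of -0.14. The fall of the sum rested on the 4 most abundant loci, a split chosen after their values were seen, at 529 ± 28.5 and 197 ± 2.66 CPM. The other 18 summed to 202 ± 9.89 and 245 ± 13.3 CPM, and no explanation was tested. They include a chromosome Y locus with unstable counts, at 0.144 and 18.3 CPM, which was among the 4 that rose. The other unannotated loci summed to 1580 ± 43 and 1020 ± 12.5 CPM.

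Counts of 184 genes, Gapdh, Rps18 and Hnrnpu among them, swung over 3-fold between libraries of 1 state. The median of their mean counts was 112 per library. It cannot decide on low counts as a cause, since the definition itself needs a library above 3 CPM. These genes lay together in the genome, with 127 of the 184 within 100 kb of another. In 1000 random sets matched on expression the median was 8 and the highest 25, so a cause acting on stretches of the genome is a candidate. Shared sequence is another. It was measured only between the longest GENCODE M21 transcripts, so the shares below do not bound read sharing with copies outside them. Of the 168 unstable genes with a value 9.52% had at least 50% of their words in another gene. The share was 4.88% of 1517 matched stable genes (Fisher's exact test, odds ratio 2.05, interval 1.09 to 3.67). Intervals of odds ratios take genes as independent, though the unstable genes lay together, so they may be too narrow. A gene model overlapping or within 1 kb stays open (odds ratio 1.27, interval 0.916 to 1.77), while overlap alone was found in 40.8% of both unstable and matched stable genes (odds ratio 0.998, interval 0.722 to 1.37). Psmb6 lies in such a stretch and of the 13 other core subunits 8 fell by less, 1 rose and 4 did not pass. Their median was -0.18 (camera adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation over the added lists or 0.39 over all 39). That median argues against a fall of the whole proteasome core by a log2 of 1 or more. Whether the fall of Psmb6 is of the same kind as the swings stays open, since its own CPM swung by at most 1.33-fold within a state. No other biological explanation was tested.

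The higher fibroblast markers may come from fewer tumour cells, from more fibroblasts, or from the activated cells themselves, and the tables did not decide. Fewer tumour cells would raise the markers of every other cell type alike. The fibroblast median exceeded that of 10 endothelial markers, -0.05, by 0.67 (interval 0.4 to 1.22), but 8 of these were under 5 CPM, near the floor. It exceeded that of 48 markers of endothelial, pericyte, adipocyte, muscle and myeloid cells by 0.43 (0.17 to 1), of which 25 were under 5 CPM. Among markers above 5 CPM alone the difference was 0.35 and its interval, -0.05 to 1.04, included 0, which keeps this explanation open. More fibroblasts would raise each marker by a common factor, and the rises differed, with a heterogeneity ratio of 52.5, which a baseline of these transcripts in tumour cells would also give. A change of state in the activated cells, which the design names, stays open and untested.

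A trend with GC content or transcript length was argued against as the whole cause of the shifts of 3 lists. After its removal the median was 2.2 for the mitosis list (interval 1.99 to 2.42), -0.74 for the p53 targets (-0.89 to -0.4) and -0.6 for the detoxification list (-1.27 to -0.16). For the detoxification list the removal took 0.05 off the size of the median (interval -0.01 to 0.05), where 0.45 would have brought it within 0.2 of 0. Over all genes with a value the rank correlation of the fold change was -0.03 with GC content and 0.05 with length.

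The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7236 genes, and 1 of the 10 splits, the real one, gave as many. The highest other split gave 1 gene.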
